A study of Mus musculus with 10 samples.

How the data were processed

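Liver RNA from 5 Slc13a5 knockout and 5 wild-type mice was measured, per the labels, on Illumina MouseRef-8 v2 bead arrays, where each probe is read out by several beads and labelled RNA binds to it in 1 colour. The genotype and replicate number of each array came from its title. The replicate numbers differ between the genotypes. Slide positions are not given in the sources used here, so a slide effect could not be tested.

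The deposited table gives, per the file headers, an average bead intensity and a detection p-value for each of 25697 probes on each array. BeadStudio 3.4.0 is named in the submitters' processing notes. No intensity was at or below 0, array medians ran from 108 to 131 units, and no normalization between arrays was visible in the values. The detection p-value compares a probe with the negative controls of its array, and had steps of 0.00125. A second deposited table holds a score per probe and array. Compared with the first table, this score was the z-score of log10 intensity within each array, recomputed with a largest difference of 4.97e-08, so its scale, centring and direction are known. Array medians of the score ran from 0.183 to 0.327. It was given for 13283 probes and blank for 12414, and 0 of the blank probes had a detection p-value of 0.02 or less on any array. The rule behind the blanks is not given in the sources used here.

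Intensities were background corrected with limma's neqc (version 3.58.1, R 4.3.3), which infers the negative controls from the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale. The offset draws small folds of dim genes towards 0. A probe was kept if its detection p-value was below 0.05 on at least 5 of 10 arrays, which left 11058 probes. Probes were given current symbols by Entrez ID through a RefSeq gene table of GRCm38.p6. Of 25697 probes 23681 matched and 2016 kept the file's symbol, and 4172 symbols were updated. A gene was represented by its probe with the highest mean over all arrays, which gave 8360 genes. For 1994 genes with more than 1 detected probe, the probes differed in sign in 761, and disagreement is stated for named genes where it was large. Between 41.3% and 43.8% of probes were detected per array. No 2 arrays held identical values, and their correlations on log2 intensity ran from 0.971 to 0.996.

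The genotypes were compared with lmFit and eBayes in limma, with genotype as the single term, and p-values were adjusted by the Benjamini-Hochberg method. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured genes. The 50 lists of pathways, cell types and checks, the tests, the samples and the alternatives were fixed before the data were examined. 6 lists had fewer than 5 measured genes and were not tested with camera. The 3 lists of the respiratory chain and ATP synthase were also joined into 1 list, as planned. Principal components and array measures were compared with two-sided exact permutation tests over all splits of the 10 arrays. An array was called an outlier of its genotype by Dixon's ratio. Named genes were fixed by a rule: genes past the adjusted threshold, or else the 8 with the smallest p in each direction, up to 4 genes of smallest p from each list, and a set of metabolic genes. Acaca, Fasn and Cpt1a of that set were not measured. Some genes that meet the rule are not reported here.

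On simulated arrays with the real means and residual spread of the 8360 genes, limma recovered 34.0% of 50 genes changed by 0.5 on the log2 scale, 86.0% of 50 changed by 1, 82.0% of 50 changed by -1 and 100% of 50 changed by 2. It also called 10 unchanged genes among 162 calls. Camera found the 1 shifted list and 0 of 44 others. The simulation drew genes independently, so it says nothing about correlated genes or arrays that stand apart.

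The alternatives were no background correction, normexp without control information (offset 50), median scaling, z-scores within arrays, the authors' scores, no detection filter, detection below 0.01 on at least 8 arrays, all probes separately, the mean of a gene's probes, a variance trend with robust moderation, array weights, leaving out each array, an adjusted p below 0.1, an unmoderated test, camera with an estimated correlation, and fry. Chosen after seeing the data were the array's upper-quartile signal as a covariate, removal of each array's trend on probe position, leaving out 2 arrays together, and an exact permutation of list means. The position of a probe is its start in the transcript, per the file headers.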

Results

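Gene expression was measured in the livers of mice that lack Slc13a5 and of wild-type mice. Slc13a5, also called mINDY, is a sodium-coupled transporter that carries citrate into hepatocytes. The mice were 3 months old, per the labels, and the strain is given as C57B/6J. Total RNA from 5 knockout and 5 wild-type livers was hybridised to 10 one-colour Illumina MouseRef-8 v2 bead arrays, 1 array per sample, each named here by its genotype and the replicate number in its title. The design text describes the samples as coming from separate mice. The table held 25697 probes, of which 10611 to 11245 were detected per array. The upper-quartile signal was 314 ± 30.5 on wild-type arrays and 278 ± 48.5 on knockout arrays (mean ± SD, n = 5 each, two-sided exact permutation p = 0.206, adjusted p = 0.275 over 4 array measures). The number of arrays limits the precision. Values below are log2 differences, knockout minus wild type, with the standard error from limma, and n = 5 livers per genotype throughout.

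The comparison asks how the liver transcriptome differs without the transporter, and the series title sets the model beside dietary restriction. No probe analysed here was named for Slc13a5, so the deleted gene could not be used to check the genotype labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty passed the detection filter, with differences from -0.22 to 0.13.

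As groups, cholesterol synthesis genes, NRF2 and glutathione genes and MHC class II genes were higher in knockout livers in limma's camera with a preset correlation (adjusted p = 0.182, 0.182 and 0.289 with an estimated correlation). No single gene passed the threshold over all genes. Among 8360 genes tested, limma gave 0 genes at a Benjamini-Hochberg adjusted p below 0.05, and 956 genes at an unadjusted p below 0.05, where 418 would be given by chance. Of the 956, 445 were higher and 511 were lower in knockout livers (430 and 964 on z-scores within each array, 468 and 1056 on the authors' scores). An unmoderated equal-variance test on the same values also gave 0 genes after adjustment. Other settings moved this count, most of all limma's array weights, which gave 274 higher and 123 lower genes. Leaving out wild-type array 3 gave 16 higher genes and 1 lower gene, and leaving out knockout array 2 gave 4 higher genes and 1 lower gene. For 197 genes (2.36%) the values of the genotypes did not overlap, against 0.794% by chance.

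Among the 8 genes with the smallest p of those higher in knockout livers were Adh7, Apcs, Gsta2, Dhcr7, Gemin2, H2-Aa and Selk. Apcs, the pentraxin serum amyloid P, differed by 1.18 ± 0.21 (limma adjusted p = 0.116) and Adh7, an alcohol dehydrogenase, by 0.98 ± 0.17 (limma adjusted p = 0.116). For both, all 5 knockout values lay above the highest wild-type value. Gemin2 (named Sip1 in the file) differed by 0.74 on its brighter probe and by 0.20 on a second probe, and Selk, a selenoprotein of the endoplasmic reticulum, by 0.96. The 8 genes with the smallest p among those lower in knockout livers were Nrep, Zfp688, Car2, Ppp1r15b, Krt23, Inmt, Zfyve27 and Ralgapa2. Nrep (named D0H4S114 in the file) had the smallest p of all genes, with a mean of 10.39 ± 0.30 in wild-type and 9.20 ± 0.29 in knockout livers (SD) and a difference of -1.19 ± 0.17 (limma adjusted p = 0.0731). Car2, a carbonic anhydrase, differed by -0.70 ± 0.13, Zfp688 by -0.67, Inmt, an amine methyltransferase, by -0.65, and Krt23 by -0.97. The probes of Car2 and Zfp688 were dim, so their differences are uncertain. Without wild-type array 3 and knockout array 2, Car2 had means of 6.33 in wild-type and 5.56 in knockout livers. Zfp688 had 6.12 and 5.38. Ppp1r15b and Zfyve27 each differed by -0.58, and Ralgapa2 by -0.94. In each of these 8 genes all 5 knockout values lay below the lowest wild-type value. Genes picked for a small p tend to separate in this way, so this adds no evidence, nor does it for Apcs and Adh7. None of these genes passed the threshold.

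Genes of cholesterol synthesis were higher in knockout livers, by a mean of 0.48 over the list. Of 20 measured members 18 were higher and 2 lower, 10 of the higher ones at an unadjusted p below 0.05. Over all genes 0 members passed in limma, and 8 passed when adjusted over the list alone, all of them higher. Dhcr7, which makes cholesterol from 7-dehydrocholesterol, differed by 0.89 ± 0.17, farnesyl diphosphate synthase (Fdps) by 0.86 ± 0.18, and the sterol reductase Tm7sf2 by 0.54 ± 0.13 (limma adjusted p = 0.144, 0.197 and 0.237). The list passed limma's camera test with a preset correlation (adjusted p = 2.43e-10) and not with the correlation estimated from these arrays (adjusted p = 0.182 with an estimated correlation). The list mean was higher on 3 of 5 knockout arrays than on every wild-type array.

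MHC class II genes, which present antigen to T cells, were higher in knockout livers by a mean of 0.93, with all 6 measured members higher. Over all genes 0 members passed in limma, and 5 passed when adjusted over the list alone. H2-Aa differed by 1.33 ± 0.27, H2-Eb1 by 0.95 ± 0.22 and the invariant chain Cd74 by 1.03 ± 0.26 (limma adjusted p = 0.17, 0.225 and 0.258). A second Cd74 probe gave 1.02. The list passed camera with the preset correlation (adjusted p = 4.18e-08) and not otherwise (adjusted p = 0.289 with an estimated correlation). All 5 knockout list means lay above every wild-type one. Knockout array 6 was the highest, and H2-Aa and H2-Eb1 stood far above the other knockout arrays on it.

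Macrophage and Kupffer cell markers were higher by a mean of 0.49, with 15 of 15 members higher, 0 past the threshold over all genes and 4 when adjusted over the list alone. The mean was 0.39 without wild-type array 5 and 0.36 without knockout array 10. The list mean was higher on 3 of 5 knockout arrays than on every wild-type array, and on knockout array 2 it lay at -0.04 from the wild-type mean. Cd68 differed by 0.86 ± 0.23 and Adgre1, which encodes F4/80, by 0.73 ± 0.24. Camera gave an adjusted p of 5.1e-07 with the preset correlation (adjusted p = 0.474 with an estimated correlation). The markers with the highest signal moved less: Vsig4 differed by 0.29, C1qb by 0.40, C1qc by 0.45 and Clec4f by 0.05. These were picked by signal after the values were seen. The 4 measured T and NK cell markers, too few for camera, were all higher, by a mean of 0.49 (two-sided exact permutation p = 0.0159, not adjusted). Of these, Zap70 (0.76 ± 0.26) and Ccl5 (0.86 ± 0.31) passed when adjusted over the list alone and 0 passed over all genes. The 4 neutrophil markers differed by a mean of 0.23 (two-sided exact permutation p = 0.246), and by 0.12 without knockout array 10.

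Acute-phase proteins, which hepatocytes secrete in inflammation, were higher by a mean of 0.45 (0.29 without knockout array 10), with 21 of 24 members higher, 0 past the threshold over all genes and 2 when adjusted over the list alone. Orm2 differed by 1.16 ± 0.37 and complement factor B (Cfb) by 0.54 ± 0.15, beside Apcs above. Camera gave an adjusted p of 1.85e-06 with the preset correlation (adjusted p = 0.474 with an estimated correlation). Interferon-stimulated genes were not shifted (camera adjusted p = 0.382).

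Genes of glutathione metabolism and targets of NRF2, a regulator of antioxidant genes, were higher by a mean of 0.28, with 18 of 20 members higher. Over all genes 0 members passed in limma, and 3 passed when adjusted over the list alone. The glutathione transferases Gsta2 and Gstm4 differed by 1.18 ± 0.21 and 0.60 ± 0.14 (limma adjusted p = 0.116 and 0.23). All 5 knockout list means lay above every wild-type one. Camera gave an adjusted p of 1.85e-06 with the preset correlation (adjusted p = 0.182 with an estimated correlation), and fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.0323 for this list and for no other tested alone.

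Proteasome subunits were higher by a mean of 0.19 (23 of 26 members, camera adjusted p = 0.000154; adjusted p = 0.474 with an estimated correlation). The catalytic subunit Psmb5 differed by 0.92 ± 0.25, and 0 members passed over all genes or adjusted over the list alone. Without wild-type array 5 the list mean was 0.13 and Psmb5 differed by 0.67. Genes of citrate and dicarboxylate transport and citrate use were higher by 0.22 (11 of 14 members, camera adjusted p = 0.0021; adjusted p = 0.289 with an estimated correlation). The mitochondrial aspartate-glutamate carrier Slc25a13 accounted for the largest difference there, 0.92 ± 0.19 on one probe and 0.66 on a second, and was its only member to pass when adjusted over the list alone. The mitochondrial citrate carrier Slc25a1 differed by 0.18 ± 0.16 (0.05 without wild-type array 5) and by 0.32 on a second probe.

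Respiratory chain and ATP synthase genes were higher in knockout livers by a mean of 0.21, and this rested on a single wild-type array. Of 67 measured members 56 were higher, 0 passed over all genes in limma and 1 passed when adjusted over the list alone. Ndufb9 of complex I differed by 0.88 ± 0.30, Cox7a2 of complex IV by 0.72 ± 0.23 and the ATP synthase subunit Atp5a1 by 0.78 ± 0.17 (0.54, 0.46 and 0.75 without wild-type array 5). Camera gave an adjusted p of 3.44e-05 for the 3 lists joined into 1 (adjusted p = 0.653 with an estimated correlation). The joined list mean differed by 0.01 without wild-type array 5, where camera's adjusted p was 0.811. Complex I behaved alike, with a mean of 0.24 and an adjusted p of 0.00028 with all arrays, 0.659 with an estimated correlation and 0.726 without that array. Cytosolic ribosomal protein genes, Rps3a1 among them at 0.62 ± 0.15, had a mean of 0.16 with all arrays (camera adjusted p = 0.00133; adjusted p = 0.659 with an estimated correlation) and -0.03 without wild-type array 5.

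**Figure D1:**
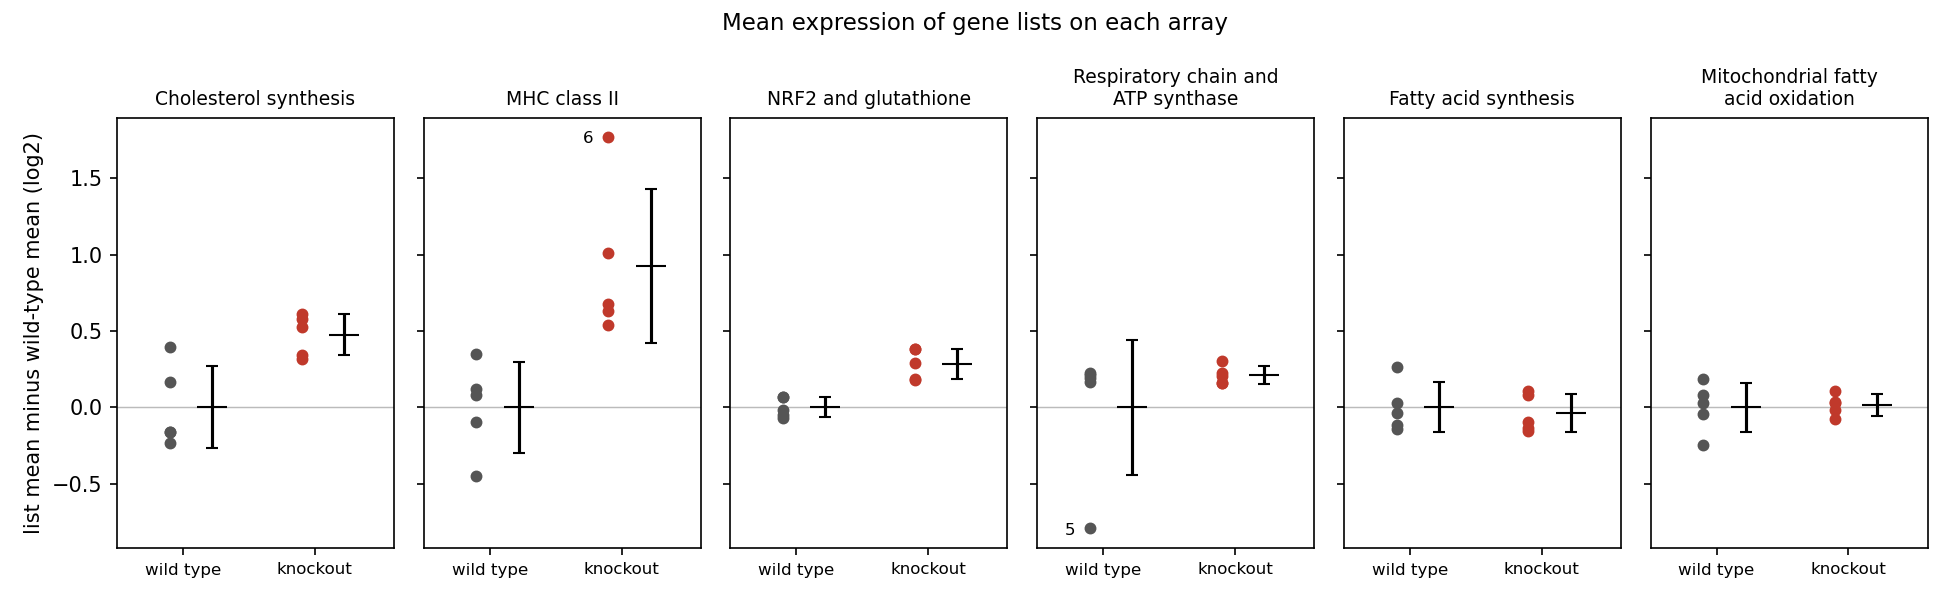
Mean log2 expression of 6 gene lists on each of the 10 arrays, minus the wild-type mean. Points are arrays, and the bars beside them show the mean ± SD of 5 arrays per genotype. Wild-type array 5 lies far below all other arrays for the respiratory chain, while all 5 knockout arrays lie above every wild-type array for MHC class II and glutathione genes.

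Wild-type array 5 differed from the other 4 wild-type arrays along the position of the probe in its transcript. Among 10 equal groups of genes ordered by probe position, the group nearest the transcript start was lower there by a median of -0.55, and the group farthest from it was higher by 0.17. Across the 8360 genes, which are not independent replicates, Spearman's rho between this deviation and the probe position was 0.37. On the knockout arrays rho lay between -0.16 and 0.18. On the other 4 wild-type arrays it lay between -0.31 and -0.09. Those 4 were compared with a mean that includes wild-type array 5, so their values partly mirror its trend.

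**Figure D2:**
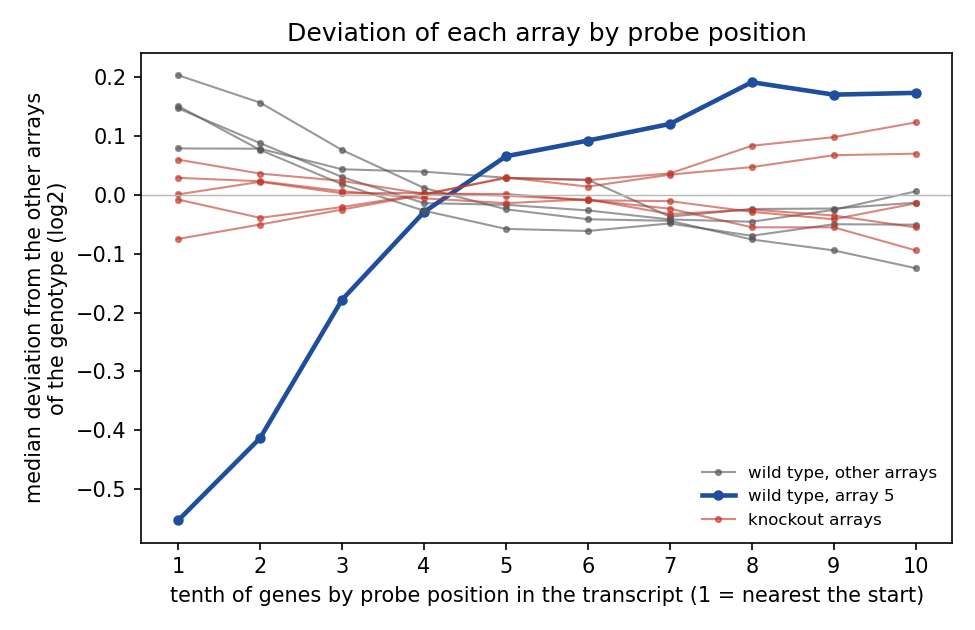
Median log2 deviation of each array from the other arrays of its genotype, for 10 equal groups of genes ordered by the position of the probe in its transcript. Each line is 1 array, and wild-type array 5 runs from -0.55 for probes nearest the start to 0.17 for those farthest from it. The other wild-type lines partly mirror that array, which is part of the mean they are compared with.

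Genes of fatty acid handling did not differ as groups. The fatty acid synthesis list had a mean of -0.04 (14 measured members, 5 higher and 9 lower, camera adjusted p = 0.798). Acly, which splits cytosolic citrate, differed by -0.03 ± 0.15 (0.05 on the authors' scale), the desaturase Scd1 by 0.03 ± 0.22, the regulator Srebf1 by -0.58 ± 0.32 and Mlxipl by -0.32 ± 0.17, of which the last 2 gave -0.26 and -0.18 without wild-type array 1. Fasn did not pass the detection filter and no probe was named for Acaca. The mitochondrial fatty acid oxidation list had a mean of 0.02 and a median of -0.02 (18 members, camera adjusted p = 0.798), with Hadhb at 0.25 ± 0.16 (0.11 without wild-type array 1). Cpt1a did not pass the detection filter. No member of either list passed over all genes in limma or when adjusted over the list alone. On the authors' values, scaled within each array, the oxidation list was higher with a camera adjusted p of 0.00068. Most tested lists were called higher on that scale, so this call is not particular to fatty acid oxidation. The median difference of all genes there was -0.04, against -0.01 in the main fit. Ketone body synthesis and PPAR-alpha target genes did not pass (camera adjusted p = 0.213 and 0.716).

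Of regulators and hormones named beforehand, the mitochondrial coactivator Ppargc1a differed by -0.05 ± 0.26, Igf1 by 0.08 ± 0.18 and Fgf21 by 0.52 ± 0.34, none of them past the threshold (limma adjusted p = 0.953, 0.883 and 0.568). A second Igf1 probe gave 0.33 ± 0.16, and Fgf21 differed by 0.27 without wild-type array 1. The mitochondrial biogenesis regulators were lower as a list by a mean of -0.14 (17 of 19 members, camera adjusted p = 0.0445; adjusted p = 0.294 with an estimated correlation), and leaving out any of 7 arrays ended that call. Its member Tfb2m, a mitochondrial transcription factor, differed by -0.27 ± 0.11. Gluconeogenesis genes were higher by a mean of 0.19 (10 of 12 members, camera adjusted p = 0.0275; adjusted p = 0.527 with an estimated correlation), with Pck1 at 0.43 ± 0.25 and G6pc at 0.26 ± 0.20 (0.24 and 0.11 without wild-type array 1). That call was lost without wild-type array 1 or knockout array 8. Genes induced by fasting and glucocorticoids were higher by a mean of 0.34 (17 of 23 members, camera adjusted p = 0.00236; adjusted p = 0.527 with an estimated correlation), with Igfbp1 at 1.26 ± 0.39. In the 3 lists of this paragraph 0 members passed over all genes or adjusted over the list alone.

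Circadian clock genes were lower by a mean of -0.21 (10 of 13 members, camera adjusted p = 0.0288; adjusted p = 0.575 with an estimated correlation). The clock outputs and regulators Per3, Per2 and Dbp differed by -0.81 ± 0.22, -0.66 ± 0.19 and -0.47 ± 0.14. These 3 passed when adjusted over the list alone and 0 passed over all genes in limma. The call for the list was lost without wild-type array 5 or 9 or knockout array 2 or 6.

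In all, 19 of 44 tested lists passed camera with the preset correlation, 17 of them higher and 2 lower in knockout livers. When the arrays were split in other ways, the same test passed a median of 12 lists and at most 21. The number of calls is thus weak evidence of a genotype difference. With an estimated correlation 0 lists passed in limma's camera, 5 had an unadjusted p below 0.05, and fry gave 1. Of the 19 calls, 8 held with each of the 10 arrays left out in turn: cholesterol synthesis, MHC class II, macrophage markers, acute-phase proteins, NRF2 and glutathione, proteasome, citrate transport and use, and fasting genes. Without wild-type array 5, 7 were lost.

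The genotypes did not separate along the first 3 principal components, which held 35.6%, 17.6% and 15.2% of the variance. Two-sided exact permutation tests gave p = 0.0794, 0.198 and 0.349, and adjusted p = 0.238, 0.298 and 0.349. The smallest p that 5 against 5 arrays can give is 0.00794. Wild-type array 5 had a score of -43.3 on the first component, where the other 9 arrays lay between -3.47 and 19.6.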

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

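The tests of wild-type array 5, of Kupffer cells and of macrophages were chosen after the results were seen, as was that of lists for exchanged samples, and the test of exchanged samples was set up after the counts for other splits were seen. Among 126 groups of 5 values examined, 13 held an array far from the others of its genotype, where chance gives about 6.3. Wild-type array 5 accounts for 5 of them and knockout array 2 for 3.

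Wild-type array 5 had low values for Ndufb9 (7.28) and Cox7a2 (7.19), a low mean of the joined respiratory chain and ATP synthase list (10.78), a score of -43.3 on the first principal component and a high value for Acly (12.45). The joined list deviated there by -0.99 from the other 4 wild-type arrays (SD 0.02 among those 4), and without this array the mean difference between the genotypes was 0.0123 against 0.21 with it, a ratio of 0.0583 that argues against a difference shared by all arrays. Low signal of short transcripts on this array may explain part of it: the listed genes had a median probe position of 369 against 1855.5 for all genes, and 741 other genes with probes near the start deviated by a median of -0.41. Once the trend on probe position was removed, the mean difference was 0.10 and the list still deviated by -0.567 on this array, which argues against that trend as the whole cause. The state of that mouse and the quality of its RNA stay open.

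Knockout array 6 had high values for H2-Aa (9.42) and H2-Eb1 (9.59) among the MHC class II genes. Signal strength of the arrays is argued against as the whole cause of the higher MHC class II genes, since the mean difference was 1.04 with the upper-quartile signal as a covariate, against 0.93 without it. More resident Kupffer cells would raise their markers alike. The 5 macrophage and Kupffer cell markers with the highest signal, picked after the values were seen, had a median difference of 0.29. The MHC class II genes had 0.95. Lyz2, among the 5, gave 0.11 on its brighter probe and 1.00 on a second. The gap within arrays was larger in knockout livers by 0.67 (two-sided exact permutation p = 0.0238), and by 0.53 without knockout array 6. The list they come from does not tell resident Kupffer cells from other macrophages. These 5, picked by signal, therefore cannot decide whether more Kupffer cells are the whole cause. More macrophages of any kind may remain, since all 15 markers were higher, by a median of 0.52 and by 0.86 for Cd68, and the gap to all 15, 0.44, had a two-sided exact permutation p of 0.0794. A change in the state of antigen-presenting cells, or more cells such as dendritic or B cells, stays open too: the 4 measured T and NK cell markers differed by a mean of 0.49, and the 1 measured B cell gene, Cd79b, by 0.10, or -0.03 without knockout array 2.

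Knockout array 2 had low values for Cfb (10.86), Slc25a13 (7.19) and Psmb5 (9.51), towards those of wild-type livers. Exchanging the labels of this array and wild-type array 3 gave 1353 genes with an unadjusted p below 0.05, against 956 under the deposited labels, and leaving both out gave 40 higher and 6 lower genes at an adjusted p below 0.05, the most of 25 pairs left out (others 0, 1 or 6 genes); exchanging wild-type array 3 with knockout array 4 gave 1276 genes, and wild-type array 7 with knockout array 2 gave 1079. A swap of these samples stays open as a candidate explanation: on genes chosen from the other 8 arrays, with wild type set at 0 and knockout at 1, knockout array 2 lay at 0.453 and wild-type array 3 at 0.664, where both are on the side of the other genotype, but within or near 1 SD of the midpoint (0.201 and 0.144 for the other arrays of each genotype), against 0.861 to 0.943 for wild-type array 3 and 0.28 to 0.331 for knockout array 2 when held out with other arrays. Of 9 lists separated by the other 8 arrays, 2 had both arrays on the side of the other genotype and 3 on that of their own, among them MHC class II (0.54 and 0.14) and NRF2 and glutathione (0.63 and 0.26 for knockout array 2 and wild-type array 3), so variation between livers that runs along the same genes stays open too, the deleted gene could not be read, and the deposited labels were kept throughout.

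Of 100 of the 126 splits of the arrays, 3 gave as many genes with an unadjusted p below 0.05 as the real one, itself included. The highest other split, 1353, is the exchange above. With the 6 exchanges of single arrays that were not drawn, it was 4 of 106. As 20 splits were not fitted, the share over all 126 is not known, and chance was not excluded for the 956 genes. For the 19 lists past the threshold, 7 of 100 splits gave as many, up to 21, so that chance was not excluded for the number of lists. For the 397 genes called with array weights, 4 of 100 splits gave as many, and the highest other split gave 890 genes.

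Gstm4 was low on knockout array 10 (8.62), on which the fewest probes among knockout arrays were detected (10661). Glul was high on wild-type array 3 (5.98).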

How the results depend on the processing

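The covariate, the position trend, the exact test of list means and leaving out 2 arrays together were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. The slide as a block was not run, nor any alternative for Slc13a5 itself. Few arrays and signal near background limit dim genes. The cause of the changes below was not tested, unless the setting itself shows it. The principal components kept their side of the threshold in every setting run. For 49 named genes, 765 of 778 values in other settings kept their direction.

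The count of genes past the adjusted threshold, 0 in each direction, became 1 higher and 1 lower gene with no background correction, 1 and 1 with normexp without control information, and 1 and 1 at an adjusted p below 0.1. It became 0 higher and 1 lower with median scaling, and likewise 1 lower with the variance trend and robust moderation. Array weights gave 274 higher and 123 lower, and leaving out wild-type array 3 and knockout array 2 together gave 40 and 6. Leaving out each array in turn gave 0 to 16 higher genes and 0 to 1 lower gene.

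At an unadjusted p below 0.05, against 445 higher and 511 lower genes, array weights gave 963 and 1062, no detection filter, which tests more genes, gave 763 and 934, and leaving out the 2 arrays gave 687 and 813. Z-scores gave 430 higher and 964 lower, the authors' scores 468 and 1056, and the signal covariate 370 and 293. With each array left out there were 271 to 692 lower genes.

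Against 17 higher and 2 lower lists, z-scores gave 28 higher, the authors' scores 27 higher and 1 lower, and array weights 11 higher. There was 1 lower list with no detection filter, the stricter filter, the signal covariate and the position trend removed. Camera with an estimated correlation gave 0 higher and 0 lower, fry 1 and 0, and the exact test of list means 0 and 0. Leaving out each array gave 11 to 19 higher and 0 to 2 lower lists.

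The leading lists lost their call in the tests that keep the correlation between genes, except NRF2 and glutathione in fry. With an estimated correlation camera's adjusted p was 0.182 for cholesterol synthesis, 0.289 for MHC class II, 0.474 for macrophage markers, 0.474 for acute-phase proteins, 0.182 for NRF2 and glutathione and 0.653 for the respiratory chain and ATP synthase. With fry these were 0.0505, 0.0829, 0.308, 0.299, 0.0323 and 0.619, and with the exact permutation test 0.131, 0.116, 0.306, 0.131, 0.116 and 0.584. MHC class II and NRF2 reached the smallest p that 5 against 5 arrays can give, 0.00794, as did the proteasome, and over 44 lists a single list at that p cannot pass on its own. In all other settings run, the first 5 lists kept an adjusted p of 0.00923 or less, while the respiratory list reached 0.551 with array weights, and 3.94e-07 to 0.811 with each array left out.

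The list of mitochondrial fatty acid oxidation passed, higher in knockout livers, with z-scores (adjusted p = 0.000273) and the authors' scores (0.00068). It turned lower, short of the threshold, with no detection filter (0.631), the signal covariate (0.972), the position trend removed (0.878) and the 2 arrays left out (0.804). With each array left out it ran from 0.274 to 0.971, and turned lower without wild-type array 1 or 3 or knockout array 2. Fatty acid synthesis turned higher, short of the threshold, with z-scores (0.419), the authors' scores (0.667), array weights (0.907) and the position trend removed (0.824), and ran from 0.552 to 0.984 with each array left out, turning higher without wild-type array 5.

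Genes with differences near 0 changed sign. Acly gave 0.05 with z-scores and with the authors' scores, 0.0585 with array weights, 0.0597 with the position trend removed, and -0.0736 to 0.0833 with each array left out. Ppargc1a gave 0.0073 with the signal covariate, 0.0041 with the position trend removed, and -0.22 to 0.10 with each array left out. Scd1 gave -0.11 with the signal covariate and -0.0502 to 0.21 with each array left out. Igf1 gave -0.12 with array weights, -0.0439 with the position trend removed, and -0.0829 to 0.18 with each array left out.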

Other observations

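The signal covariate and the removal of the position trend were chosen after seeing the data, as was the count of genes near Slc13a5.

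Further groups of liver genes passed camera with the preset correlation and did not pass with an estimated one. Xenobiotic genes driven by CAR and PXR were higher in knockout livers by a mean of 0.22 (14 of 16 members, adjusted p = 0.008; adjusted p = 0.527 with an estimated correlation). Urea cycle and amino acid breakdown genes were higher by 0.16, or 0.09 without knockout array 8 (20 of 25 members, adjusted p = 0.008; adjusted p = 0.527 with an estimated correlation). Heat shock proteins were higher by 0.24 (7 of 9 members, adjusted p = 0.0198; adjusted p = 0.474 with an estimated correlation). The call was lost without wild-type array 9 for the first list, without knockout array 8 for the second, and without wild-type array 1 or knockout array 8 for the third. Endothelial markers were higher by 0.14, or 0.08 without wild-type array 5 (adjusted p = 0.0362; adjusted p = 0.474 with an estimated correlation) and mitochondrial ribosomal proteins by 0.09, or -0.04 without wild-type array 5 (adjusted p = 0.0492; adjusted p = 0.736 with an estimated correlation). Both calls were lost without wild-type array 5, knockout array 2 or knockout array 8.

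Some single genes of lists that did not shift are of interest to liver biology, none of them past limma's threshold over all genes. Cyp17a1, a steroid hydroxylase of the female-biased list, differed by 1.26 ± 0.37 (limma adjusted p = 0.298), and Hsd3b5 of the male-biased list by -1.42 ± 0.58 (limma adjusted p = 0.392). Without knockout array 8 these differences were 0.93 and -0.92. The 2 lists had camera adjusted p of 0.382 and 0.152, both with lower means in knockout livers. The male-biased list was lowest on knockout array 8 and had a mean of -0.06 without it against -0.26 with all arrays. Without knockout array 4 its mean was -0.40 and it passed at the preset correlation (camera adjusted p = 0.00494). With all arrays and an estimated correlation its camera adjusted p was 0.684. Glul, the glutamine synthetase of pericentral hepatocytes, differed by 0.53 ± 0.16 (limma adjusted p = 0.298). Its probe was dim, with a highest wild-type value of 5.98, so this difference is uncertain. The pericentral and periportal lists did not pass (camera adjusted p = 0.382 and 0.476). The TCA cycle, hepatocyte and stellate cell lists did not pass either (camera adjusted p = 0.229, 0.116 and 0.116), though the second passed without knockout array 2 (0.0361) and the third without wild-type array 3 (0.0415), knockout array 4 (0.0378) or knockout array 10 (0.0449).

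The mean difference of the cholesterol synthesis list was 0.48. It was 0.36 ± 0.13 (SE) with the array's upper-quartile signal as a covariate and 0.47 ± 0.14 once each array's trend on probe position was removed. Camera's adjusted p at the preset correlation was 5.58e-07 and 5.16e-10. Given the SE of the first value, how much of the difference goes with signal strength could not be told.

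Of 156 genes within 10 Mb of Slc13a5 on its chromosome (GRCm38.p6), 12.2% had an unadjusted p below 0.05, against 11.5% of 7476 genes elsewhere (one-sided Fisher's exact p = 0.434). The planned list of neighbouring genes was not shifted (camera adjusted p = 0.835).

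Without wild-type array 3 and knockout array 2, 46 genes passed limma's adjusted threshold, the most of 25 pairs left out, of which the others gave 0, 1 or 6. They included Atp5a1 (1.00 ± 0.13), Slc25a13 (1.14 ± 0.16), Apcs (1.42 ± 0.19), Nrep (-1.35 ± 0.18) and Ppara (-0.88 ± 0.15, against -0.40 with an unadjusted p of 0.25 with all arrays), of which Ppara was picked after its value was seen. The pair was chosen after the data were seen, and the standard errors and adjusted p-values take no account of that choice, so they are no evidence for these genes.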
